A study of Mus musculus with 6 samples.

How the data were processed

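Liver RNA was measured in 6 samples from mice of the Townes sickle cell model, in which human globin genes replace the mouse ones. Per the labels, 3 libraries came from SS mice, homozygous for the sickle beta-globin allele, and 3 from AS mice, which carry a sickle and a normal beta-globin allele. The samples were total RNA from liver at 7 months of age. The labels give no sex, litter, batch or day, and do not say whether replicates are separate animals, so the p-values measure only the spread between these samples.

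The authors deposited 1 table of raw read counts per sample, with 24421 gene symbols in each. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 and counted with HTSeq. Tool versions, the gene annotation, strand settings and read filters were not given in the sources used here. Reads that match near-identical gene copies may be dropped or split by such counting, and without a strand setting a gene cannot be told apart from an antisense partner. Each table ends with 5 counter lines for records outside genes, which were kept out of library sizes and tests. Those records made up, on average, 41.6% (no annotated gene), 20.1% (several alignments), 3.72% (not aligned), 2.71% (low alignment quality) and 0.527% (ambiguous) of AS records. The SS averages were 46.9%, 15.4%, 5.05%, 3.26% and 0.384%. The widest Wilson 95% interval of these shares was 0.0425 percentage points. The counters tally alignment records, so these are shares of records and not strictly of reads. Reads are not counted as unique molecules, so intervals and count floors here cover counting error alone.

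Gene counts per library ran from 6670011 to 13700194. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12622 genes holding 99.8% of gene reads. SS was compared with AS by edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) factors, a robust quasi-likelihood fit and a two-sided F-test, adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. CPM, the gene counts scaled to a common library size, was computed with the same factors, and is given as the mean ± SD of 3 libraries. The standard error (SE) of a log2 fold change was derived from its F statistic.

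Gene lists for liver functions, bile transport and the cell types that a liver piece can hold were fixed before the data were examined, 32 in all. The 31 lists with at least 3 members tested were compared with all other genes by limma's camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. Camera was also run with an estimated correlation, and fry as a directional test of each list alone. Pancreatic acinar markers had 2 members tested and no list test. Beside the count of called members over all genes stands the count adjusted over the list alone. Several lists share genes: Cyp7b1 and Slco1a1 stand among both bile genes and male-biased genes, for example.

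The rule for genes named in the text was fixed before the data were examined. It took the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out gene models without a symbol-like name. It also took 10 bile and heme genes whatever their result, up to 3 called members of each primary list or otherwise the member with the lowest p, and 2 called members of each other list. Of the genes this rule takes, 1 is not reported here. Mouse globin and sex chromosome genes were named for their values. Any other gene named in the text was chosen after its values were seen, as a called gene, as a member of a list described there or as an abundant transcript.

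Coordinates, exon lengths and GC content came from GENCODE on the same mouse build. Of the symbols, 23336 matched directly and 668 by an older symbol, while 417 did not match or lay at several loci. In tests on counts simulated from these libraries with 200 of 12622 genes changed, the procedure found 5.6% of genes changed 2-fold and 66.8% of those changed 4-fold. It made 7.4 false calls on average over 5 runs and gave 0 calls the wrong sign. With no gene changed, it made at most 5 calls. A simulated list of 20 genes raised 1.5-fold was called in 5 of 5 runs with the preset correlation and in 0 of 5 with an estimated correlation. The simulated genes varied independently of each other, whereas real lists had estimated correlations of up to 0.584 (neutrophil markers). These runs therefore do not show how the gene and list tests behave when genes vary together.

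Alternatives were fixed before the data were examined: median-ratio, upper-quartile and no scaling factors, no filter and a stricter filter (at least 1 CPM in 3 libraries), a replicate block, a non-robust fit, each library left out in turn, a 2-fold threshold, DESeq2 1.42.0 and limma-voom. Further alternatives were chosen after seeing the data: AS replicate 1 and SS replicate 3 left out together, AS replicates 2 and 3 summed, and trends on exon length or on GC content removed. A planned sex term was not run, because each Y-linked gene measured held at most 4 counts over the 6 libraries together, and Xist was present in each. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made the plots.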

Results

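Gene expression was measured by RNA sequencing in liver from mice with sickle cell disease. All mice belonged to the Townes line, in which human alpha- and beta-globin genes stand in place of the mouse genes. SS mice carry only sickle beta-globin, while AS mice carry a sickle and a normal allele and serve as the controls. Each genotype had 3 libraries. AS replicates 1, 2 and 3 held 10424592, 6670011 and 12658869 gene reads, and SS replicates 1, 2 and 3 held 6971289, 13700194 and 10589220. Of 24421 genes in the tables, 12622 had enough counts to test.

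The adult mouse globin genes, which the model replaces in both genotypes, bear on the mouse line but cannot tell SS from AS. Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had 0 counts in all 6 libraries, although reads from near-identical copies can also be lost in counting. The embryonic alpha-like globin gene Hba-x was detected, at 4.83 ± 2.98 CPM in AS and 39.7 ± 13.8 CPM in SS (SD, n = 3), a rise of 3.05 on the log2 scale (SE 0.457, edgeR adjusted p = 0.0143), which was 3.67 without AS replicate 1 and whose call ended without AS replicate 2 or SS replicate 2. Xist, the RNA of the inactive X chromosome, stood at 516 ± 311 CPM in AS and 677 ± 252 CPM in SS, and the difference did not pass the test (edgeR adjusted p = 0.763). AS replicate 1 had the lowest value, 156 CPM, against 685 and 705 CPM in AS replicates 2 and 3. Among Y-linked genes, Eif2s3y had 4 counts and Ddx3y had 3 over all libraries, and Kdm5d and Uty had 0.

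The first principal component of log2 CPM (41.6% of the variance) put the 3 AS libraries below 0 and the 3 SS libraries above 0. AS replicate 1 and SS replicate 3 lay at its opposite ends, and the second component (24.1%) set SS replicate 3 apart from the other SS libraries. AS replicates 2 and 3 were far closer to each other than any other pair, with a chi-square of 4.05 per gene against 29.2 to 170 for the other pairs, which is still above sampling noise. The labels do not say that this pair came from separate animals, so n = 3 for AS counts libraries, and with the pair summed 31 genes were called instead of 122.

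**Figure D1:**
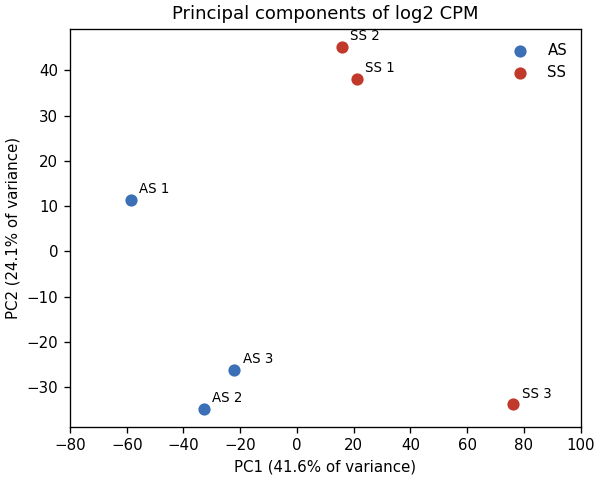
The first and second principal components of log2 CPM are plotted for the 6 libraries, with AS in blue and SS in red and the replicate number beside each point. The axes give each component's share of the variance, 41.6% and 24.1%.

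The series title names impaired bile secretion in sickle cell disease, so the comparison of SS with AS liver asks which genes differ in a liver exposed to sickling. The acute phase genes Saa1 and Saa2 rose in SS liver, as did members of the lists for red cell precursors, dividing cells and recruited macrophages. Those lists were called by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.0930, 0.0725 and 0.0725). Saa1 and Saa2, which encode serum amyloid proteins, rose 16.1-fold and 15.97-fold, and Alas2, the first enzyme of heme synthesis in red cell precursors, rose 8.79-fold. Gpnmb, a glycoprotein of lipid-laden and scar-associated macrophages, rose 62.7-fold from 0.355 ± 0.209 to 23.7 ± 15.9 CPM (SD, n = 3), a log2 change of 5.97 that was 5.27 without SS replicate 3. Mup12, a major urinary protein gene, and Sult2a8, a liver sulfotransferase, fell. The main bile salt export pump gene Abcb11 did not pass the test.

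In all, 122 genes were called, 115 higher and 7 lower in SS, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 122 differed at least 2-fold. At an unadjusted p under 0.05, 1151 genes were higher and 452 lower. Called genes lay mostly at low expression: of the 115 that rose, 68 had a mean of 1 to 10 CPM, 40 had 10 to 100 CPM and 7 had more. Among genes of at least 100 CPM, an unadjusted p under 0.05 went with a lower value in 228 genes and a higher one in 34. The count depended on the libraries: it was 22 without AS replicate 1, 26 without AS replicate 2, 38 without AS replicate 3 and 26 without SS replicate 2. It was 31 with AS replicates 2 and 3 summed and 662 (346 higher, 316 lower) with AS replicate 1 and SS replicate 3 both left out, settings chosen after seeing the data.

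**Figure D2:**
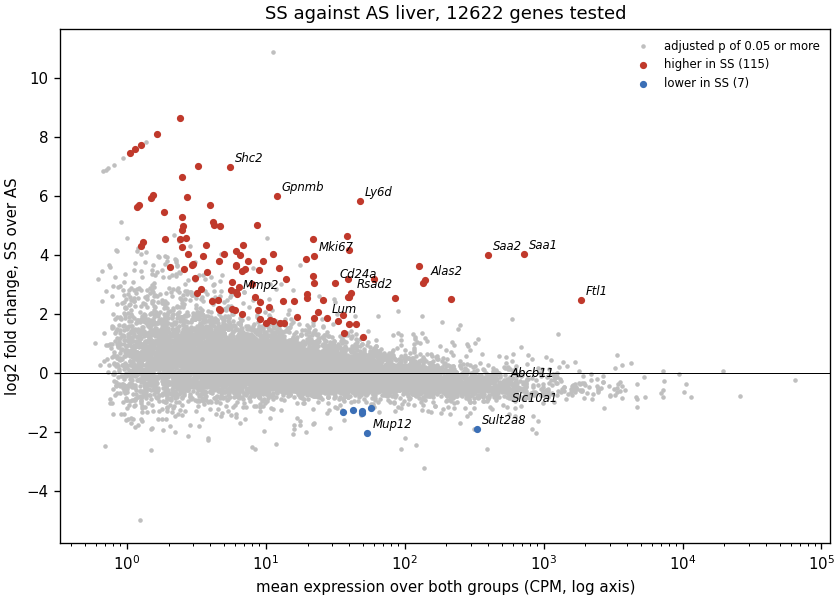
Each point is a tested gene, with its mean CPM over both groups on a log axis and its log2 fold change in SS over AS on the vertical axis. The 115 called genes that were higher (red) lie mostly at low expression, and 7 were lower (blue).

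Among called genes with a mean of at least 5 CPM in SS and separated groups, the largest rises were in Hmmr, Shc2, Gpnmb, Cdkn3, Ly6d and Hbq1a. Hmmr, a hyaluronan receptor that binds the mitotic spindle, had 1 count over the AS libraries, in AS replicate 2, and 220 over the SS libraries, a ratio of 175 with a 95% counting interval of 31 to 6930. Shc2, an adaptor of receptor tyrosine kinases, had 2 and 364 counts (ratio 145, counting interval 39.7 to 1200). Cdkn3, a cell cycle phosphatase, had 2 and 169 counts (ratio 67.1, counting interval 18.3 to 559). Ly6d, a membrane protein of the Ly6 family on chromosome 15 (74762056 to 74763620, mm10), rose from 1.64 ± 0.889 to 93.2 ± 61.2 CPM, by 5.80 on the log2 scale (SE 0.591, edgeR adjusted p = 0.00193), and by 5.14 without SS replicate 2. Hbq1a, an alpha-like globin gene, rose from 0.120 ± 0.123 to 7.89 ± 4.39 CPM (log2 change 5.69, SE 0.774, edgeR adjusted p = 0.00903), and the change was 6.65 without AS replicate 3. The calls of Cdkn3 and Hbq1a each ended in 2 of the 6 fits that left out a library, and that of Hmmr in 1.

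Among the 7 genes that fell, Mup12 (chromosome 4, 60737383 to 60741326) went from 86.9 ± 19.0 to 21.1 ± 8.52 CPM, a log2 change of -2.05 (SE 0.335, edgeR adjusted p = 0.0218). Sult2a8 went from 520 ± 81.5 to 140 ± 76.5 CPM (log2 change -1.89, SE 0.373, edgeR adjusted p = 0.0472). Acot3, a peroxisomal acyl-CoA thioesterase, changed by -1.38 (SE 0.262), Sugct, a glutarate CoA-transferase, by -1.32 (SE 0.243), and the noncoding genes BC048644 and AW495222 by -1.30 and -1.25. Mup12 and Sult2a8 belong to families of similar copies, and AW495222 is annotated as antisense, so their values are uncertain. The calls of Sult2a8, Acot3, Sugct, BC048644 and AW495222 each ended in 5 of the 6 fits that left out a library, and that of Mup12 in 3. With library totals alone the number of genes that fell was 1, and it was 0 without AS replicate 1, AS replicate 2 or SS replicate 2.

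Genes for taking up and for making bile acids fell as lists, and those for moving bile acids out of the hepatocyte did not pass the test as a list. The falls were lost with an estimated correlation (adjusted p = 0.0931 and 0.0930), and without SS replicate 3 the export list fell too (camera adjusted p = 0.0200). Abcb11, the bile salt export pump of the canalicular membrane (chromosome 2, 69238282 to 69342616), had 591 ± 79.2 CPM in AS and 472 ± 47.8 CPM in SS (SD, n = 3), a log2 change of -0.32 (SE 0.251, 95% interval -0.88 to 0.23, edgeR adjusted p = 0.607). Abcc2, which exports bilirubin conjugates, had a log2 change of 0.61 (SE 0.606, adjusted p = 0.6997 by edgeR), which rests on 575 CPM in SS replicate 3 and is -0.63 without it. Abcb4, which moves phosphatidylcholine into bile, had 0.33 (SE 0.295), which is 0.0048 without SS replicate 3, and the sterol exporter subunit Abcg8 -0.69 (SE 0.326). None of the 10 canalicular export genes was called over all genes or adjusted over the list alone (camera adjusted p = 0.314, and 0.662 with an estimated correlation). With AS replicate 1 and SS replicate 3 both left out, a setting chosen after seeing the data, the export list fell (camera adjusted p = 0.000606) and 2 members were called lower, Abcc2 (log2 change -0.91) and Abcg8 (-1.22). Basolateral efflux genes were not called as a list either (adjusted p = 0.314), with Abcc5 at a log2 change of 1.48 (edgeR adjusted p = 0.0925, DESeq2 adjusted p = 0.0240).

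Slc10a1, which encodes the sodium taurocholate transporter NTCP on the sinusoidal membrane (chromosome 12, 80953183 to 80968705), had 755 ± 33.1 CPM in AS and 334 ± 51.1 CPM in SS. Its log2 change was -1.18 (SE 0.253, edgeR adjusted p = 0.0655), so it missed the threshold over all genes, but it passed when adjusted over the list alone, as 1 of 7 members. Slc10a1 was called over all genes without SS replicate 3 (edgeR adjusted p = 0.0319) and by DESeq2 (adjusted p = 2.28e-05). All 7 sinusoidal uptake genes had lower fitted values, with a median log2 change of -0.56, and the list fell (camera adjusted p = 0.000589, adjusted p = 0.0931 with an estimated correlation). Bile acid synthesis and conjugation genes also fell as a list, with 14 of 15 members lower and a median of -0.58 (camera adjusted p = 3.27e-06, adjusted p = 0.0930 with an estimated correlation). No synthesis gene was called by edgeR in the comparison by genotype alone with all 6 libraries, while DESeq2 called 2 lower, and edgeR called 4 lower with AS replicate 1 and SS replicate 3 both left out. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 change of 0.39 (SE 0.481), which is -0.41 without SS replicate 3. Cyp8b1, which directs synthesis to cholic acid, had -1.37 (SE 0.488), and Cyp7b1, the oxysterol hydroxylase of the alternative pathway, had -2.21 (SE 0.583), with edgeR adjusted p = 0.280 and 0.137. Without AS replicate 1, which had 475 and 294 CPM of them, their log2 changes were -0.65 and -1.50, and without SS replicate 1 that of Cyp7b1 was -3.05. DESeq2 called Cyp7b1 (adjusted p = 0.00211).

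The nuclear receptors that sense bile acids did not pass the test. Nr1h4, which encodes FXR, had 140 ± 12.6 CPM in AS and 110 ± 10.2 CPM in SS (log2 change -0.35, SE 0.229, edgeR adjusted p = 0.540), and its target Nr0b2, which encodes SHP, had a log2 change of -0.79 (SE 0.376, edgeR adjusted p = 0.421). Ppargc1a, a transcriptional coactivator, had 0.89 (SE 0.409). The list of 16 sensing and hepatocyte transcription factors was not called (camera adjusted p = 0.271), although it fell without SS replicate 3 (camera adjusted p = 0.0202) and without SS replicate 3 and AS replicate 1 (0.0207). Nor were the 24 tight junction and canaliculus genes called (camera adjusted p = 0.314), where the gap junction gene Gjb2 had the lowest p (log2 change -0.86, SE 0.250, edgeR adjusted p = 0.175, DESeq2 adjusted p = 0.0142). At 3 libraries per group, a change of 2-fold is seldom detectable, so these results do not show that the genes stayed the same.

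**Figure D3:**
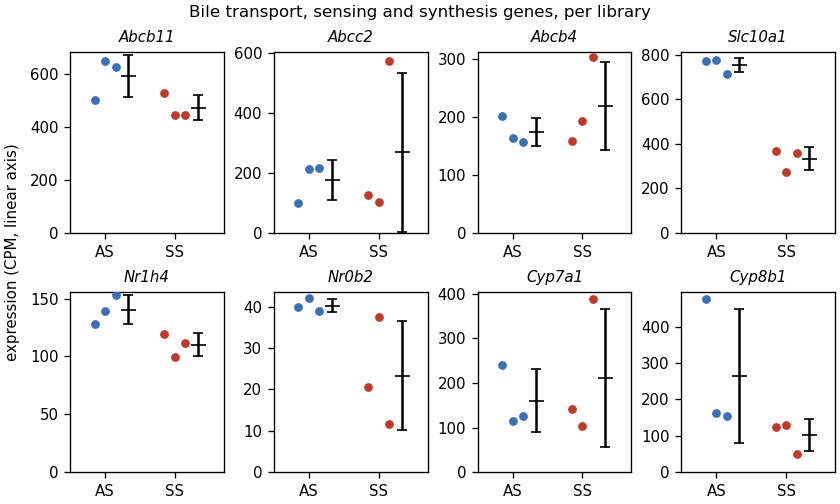
CPM on a linear axis is plotted for 8 genes of bile transport, sensing and synthesis, with 1 point per library, AS in blue and SS in red, and the mean and SD (n = 3) beside the points. The groups are apart for Slc10a1, Nr1h4, Nr0b2 and Cyp8b1, none of which passed the test over all genes, and for Abcc2 a single SS library stands at 575 CPM.

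Among markers of bile duct cells, Cd24a and Prom1 rose, and the duct keratin gene Krt19 did not pass the test. Cd24a, a surface protein of biliary progenitors that red cell precursors and leukocytes also carry, rose from 6.86 ± 1.23 to 55.9 ± 16.2 CPM (log2 change 3.03, SE 0.315, edgeR adjusted p = 0.00193). Prom1, a progenitor surface protein, rose 11.8-fold (log2 change 3.56, SE 0.494, edgeR adjusted p = 0.0103), and its call ended without AS replicate 1, AS replicate 2 or SS replicate 2. Krt19 had 1.52 ± 0.639 CPM in AS and 1.91 ± 1.37 CPM in SS, with a log2 change of 0.33 (SE 0.721), which is -0.37 without SS replicate 1. The list of 10 tested cholangiocyte markers rose (2 called, 3 adjusted over the list alone, median 0.57, camera adjusted p = 0.000182, adjusted p = 0.181 with an estimated correlation), but without SS replicate 1 its camera adjusted p was 0.101 and its median -0.24.

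Acute phase genes, which the liver makes in response to inflammation, included rises with the lowest edgeR adjusted p of all genes tested. Saa1 (chromosome 7, 46740497 to 46742980) went from 84.2 ± 12.7 to 1357 ± 307 CPM (log2 change 4.01, SE 0.315, edgeR adjusted p = 0.000432) and Saa2 (46751790 to 46754313) from 47.0 ± 7.03 to 750 ± 90.1 CPM (15.97-fold, SE 0.286 on the log2 scale). The pair are near copies that can share reads. Lcn2, a siderophore-binding protein, and Orm2, an acid glycoprotein, were the other called members. The other 16 of 20 members were not called, and the list median was 0.08. The median was -0.016, -0.017 and -0.023 without AS replicate 2, AS replicate 3 and SS replicate 2. It was 0.39, 0.13 and 0.12 without AS replicate 1, SS replicate 1 and SS replicate 3. With AS replicate 1 and SS replicate 3 both left out, it was 0.48 and 7 members were called higher. With all 6 libraries, the list's rise (camera adjusted p = 3.27e-06, adjusted p = 0.363 with an estimated correlation) rests on few genes.

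Erythroid and cell cycle genes rose together. Of 21 erythroid markers tested, 10 rose (15 adjusted over the list alone), with a median log2 change of 3.42, which is also 3.42 with the 3 members of few AS counts set at a bound (camera adjusted p = 2.33e-25, adjusted p = 0.0930 with an estimated correlation). Alas2 went from 28.8 ± 1.54 to 253 ± 68.9 CPM (log2 change 3.14, SE 0.290, edgeR adjusted p = 0.00128). Of 24 cell cycle genes, 9 rose (18 adjusted over the list alone), all 24 had higher fitted values, and the median was 2.49 (camera adjusted p = 2.90e-27, adjusted p = 0.0725 with an estimated correlation). Mki67, a marker of dividing cells, went from 2.72 ± 2.33 to 41.9 ± 12.9 CPM (log2 change 3.94, SE 0.535) and Cdc20, an activator of the anaphase complex, from 1.26 ± 0.537 to 18.02 ± 5.95 CPM (log2 change 3.78, SE 0.453). Leaving out AS replicates 1, 2 and 3 in turn left 2, 3 and 4 erythroid calls, and leaving out SS replicates 1, 2 and 3 left 7, 3 and 4. The cell cycle calls were then 2, 3 and 4, and 6, 2 and 7. The log2 change of Mki67 was 4.92 without AS replicate 1, and its call ended without AS replicate 2 or SS replicate 2, at an edgeR adjusted p of up to 0.0593. Cdc20 was not called by limma-voom (adjusted p = 0.0524).

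Myeloid and matrix genes rose as well. Of 13 monocyte and recruited macrophage markers, 6 rose (10 adjusted over the list alone; median 1.48, camera adjusted p = 1.32e-15, adjusted p = 0.0725 with an estimated correlation), among them Gpnmb (log2 change 5.97, SE 0.645, edgeR adjusted p = 0.00218) and the macrophage elastase gene Mmp12 (log2 change 3.50, SE 0.529, edgeR adjusted p = 0.0149). None of the 12 markers of Kupffer cells, the resident macrophages, was called, with a median of 0.73; the list rose (camera adjusted p = 0.00919, adjusted p = 0.543 with an estimated correlation), but had an adjusted p of 0.516 without SS replicate 2 and 0.0589 without AS replicate 3. Of 8 neutrophil markers, Mpo and Ngp, which encode granule proteins, rose (7 members adjusted over the list alone; median 4.49, or 4.01 with 2 members of few AS counts at a bound, and 3.53 over 12 members without AS replicate 1 or 3.45 over 9 without SS replicate 2; camera adjusted p = 2.47e-11, adjusted p = 0.115 with an estimated correlation). Mpo had 1 count over the AS and 85 over the SS libraries, a ratio of 67.5 with a counting interval of 11.8 to 2700, and Ngp had a log2 change of 4.53 (SE 0.788), which was 5.22 without AS replicate 1 and 3.92 without SS replicate 2. Of 24 stellate cell and fibrosis genes, Mmp2, Lum and Col1a2 rose (7 adjusted over the list alone; median 0.67, camera adjusted p = 1.69e-07, adjusted p = 0.181 with an estimated correlation). Mmp2, a gelatinase, had a log2 change of 2.67 (SE 0.388) and Lum, a collagen-binding proteoglycan, 1.86 (SE 0.276). Without AS replicate 1, 2 or 3 or SS replicate 2, 1 macrophage marker was called and 0 neutrophil or stellate genes, and limma-voom called 0 macrophage markers. Without SS replicate 3, 4 macrophage markers were called, and 1 neutrophil marker without SS replicate 1. The calls of Mmp12, Ngp, Mmp2 and Lum each ended in 4 of the 6 fits that left out a library, and that of Mpo in 6.

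**Figure D4:**
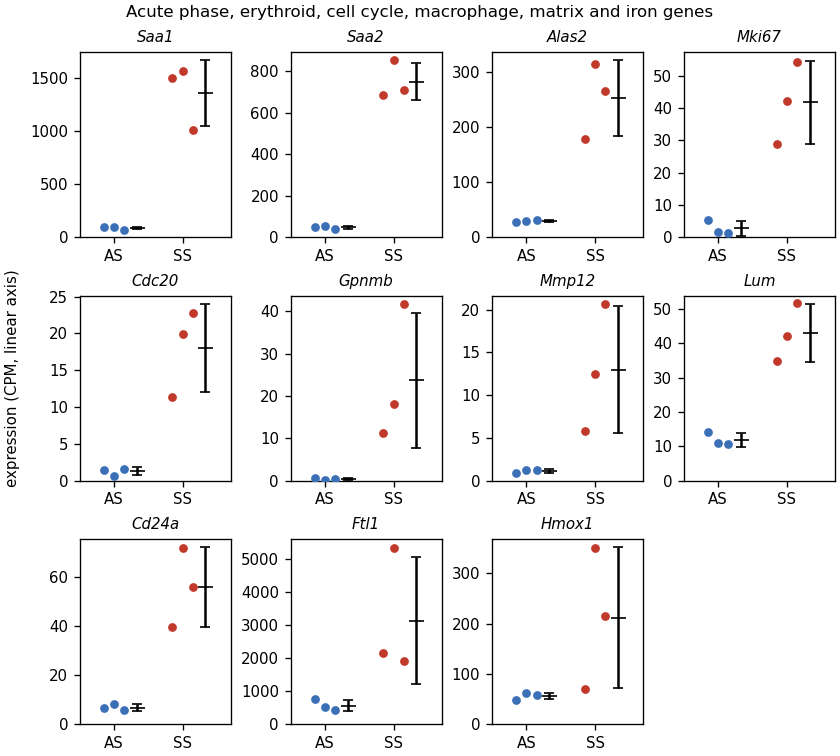
CPM on a linear axis is plotted for 11 genes of the acute phase, red cell precursors, the cell cycle, macrophages, matrix, bile ducts and iron handling, with 1 point per library and the mean and SD (n = 3) beside the points. The 3 SS points lie above the 3 AS points in each panel, and Hmox1 did not pass the test.

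In heme and iron handling, Ftl1, the ferritin light chain, rose from 567 ± 174 to 3143 ± 1919 CPM (log2 change 2.47, SE 0.438, edgeR adjusted p = 0.0339). It has near-identical copies, and its call ended in 4 of the 6 fits that left out a library, with a log2 change of 1.83 without SS replicate 2. Hmox1, which breaks down heme, had 56.4 ± 6.62 CPM in AS and 212 ± 141 CPM in SS, a log2 change of 1.91 (SE 0.472) that did not pass the test (edgeR adjusted p = 0.111), but did without SS replicate 1 (edgeR adjusted p = 0.0152) and by DESeq2 (adjusted p = 0.0034). The list of 22 genes was not called (camera adjusted p = 0.462).

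Hepatocyte metabolic lists fell, with 0 members called by edgeR in the main fit, by genotype alone with all 6 libraries and the low-count filter. DESeq2 called 5 cytochromes, 7 female-biased, 3 male-biased and 2 periportal genes lower, and edgeR with no filter called 2 cytochromes, 1 female-biased and 1 periportal gene lower. Without SS replicate 1, edgeR called 1 cytochrome and 1 female-biased gene lower, and without SS replicate 3 it called 2 female-biased genes. With AS replicate 1 and SS replicate 3 both left out, a setting chosen after seeing the data, edgeR called 8 of 10 periportal, 7 of 21 cholesterol synthesis, 7 of 17 female-biased, 6 of 15 cytochrome and 3 of 11 male-biased genes lower. They were drug metabolising cytochromes (median log2 change -0.70, camera adjusted p = 2.72e-08, adjusted p = 0.114 with an estimated correlation), female-biased liver genes (-1.18, 2.15e-14, and adjusted p = 0.0725 with an estimated correlation) and periportal genes (-0.53, 0.000173, and adjusted p = 0.0931 with an estimated correlation). Cholesterol synthesis genes had a median of -0.49 (camera adjusted p = 0.000192, adjusted p = 0.404 with an estimated correlation) and fatty acid oxidation genes -0.40 (camera adjusted p = 0.000564, adjusted p = 0.363 with an estimated correlation). Male-biased genes had -0.60 (camera adjusted p = 0.00951, adjusted p = 0.363 with an estimated correlation), and that call ended without AS replicate 1 (adjusted p = 0.200, median -0.072), SS replicate 1 (0.0619) or SS replicate 2 (0.0926). Adjusted over the list alone, 10 of 17 female-biased genes, 7 of 15 cytochromes, 3 of 10 periportal and 3 of 12 male-biased genes passed. For comparison, a set was taken of the 20 transcripts with the highest mean CPM in AS outside the 8 lists called lower. Rn45s was left out of it. The set had a median log2 change of -0.60, and ranking by AS alone can favour a fall in SS. The genes of those 8 lists had a median of -0.52.

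In total 17 of 31 lists were called, 9 higher and 8 lower, with the preset correlation. With an estimated correlation camera called 0, although 9 had an unadjusted p under 0.05, and fry called 9 (5 higher, 4 lower). The preset test also called up to 15 lists in the other splits of the 6 libraries into 3 and 3, which limits what each list call shows about genotype. Those splits have both genotypes on both sides in unequal numbers, so part of the genotype difference can remain in them.

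**Figure D5:**
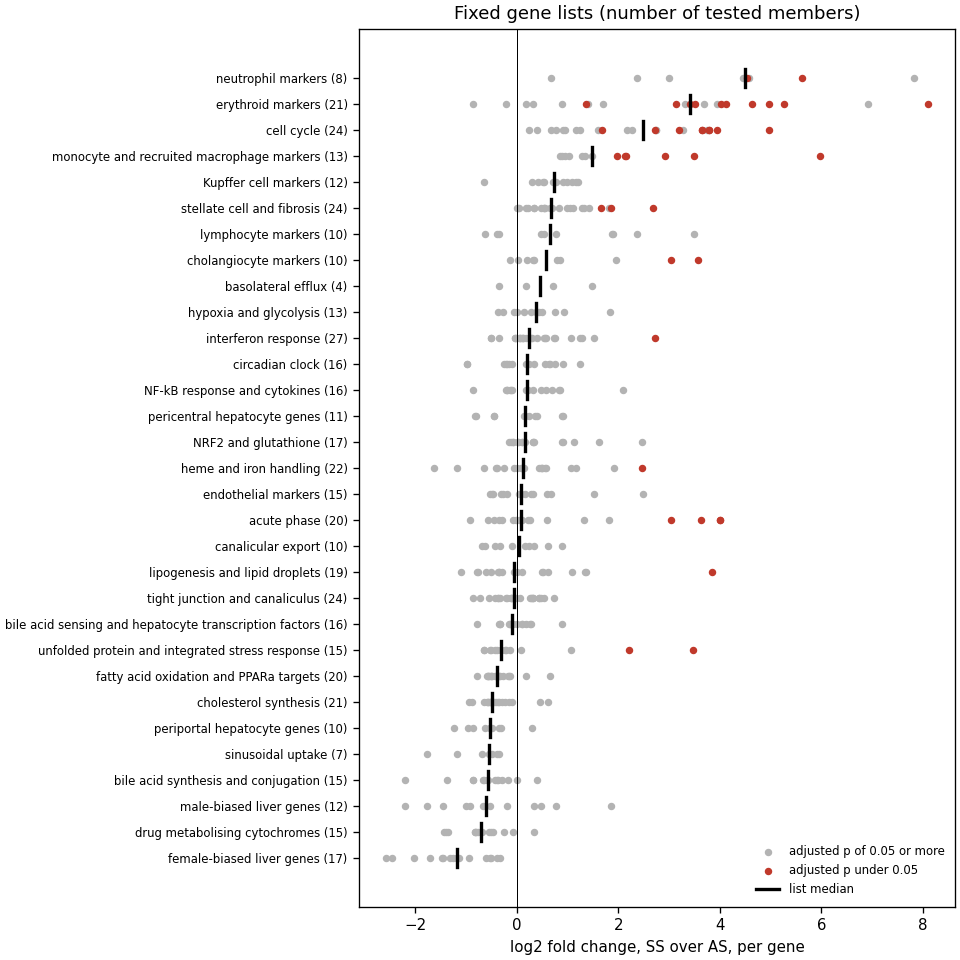
Each point is a tested gene, placed by its log2 fold change in SS over AS in the row of its list, with red for an adjusted p under 0.05 and a black bar at the list median. Neutrophil, erythroid and cell cycle lists have the highest medians (4.49, 3.42 and 2.49), although without SS replicate 2 the neutrophil median (3.45) lies below the erythroid one (3.55), and female-biased liver genes the lowest (-1.18).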

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

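The tests of stray reads, gene length, circulating blood, dilution and scaling in this part were chosen after the results were seen, while the splits of the libraries were planned before. In SS libraries, 46.9% of records on average lay in no annotated gene, against 41.6% in AS. SS replicate 1 carries most of this, at 53.9%, and without it the gap falls from 5.28 to 1.77 percentage points. The unaligned share was 5.05% in SS against 3.72% in AS. Both came up as signals in records that the comparison of genes does not use, with each SS library above each AS library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The rule looked only for shares higher in SS. The groups were also apart the other way, at the same permutation p, for several alignments (AS 18.4% to 22.8%, SS 14.7% to 16.2%) and ambiguous records (AS 0.510% to 0.537%, SS 0.291% to 0.464%).

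In SS liver, 9 of 24 cell cycle, 10 of 21 erythroid and 2 of 8 neutrophil genes were called higher. Those lists were not called by camera with an estimated correlation (adjusted p = 0.0725, 0.0930 and 0.115). Stray genomic reads are argued against by chemoreceptor genes, which had the most reads in SS replicate 1. There the 21 called members rose per kb of exon by a median of 169 times the rise of those genes. The members were chosen as called in these data, which favours a large rise. Intronic reads were not tested, since liver does not use chemoreceptor genes. A trend on gene length is argued against for these members, since with it removed their median log2 change was 3.97, against 3.78 in the main fit. All 21 of 21 kept their call. That was likely from the start, as they were chosen as called and removing the trend shifted the log2 changes of tested genes by a median of -0.069. More circulating blood in the SS pieces stays open: lymphocyte markers had a median log2 change of 0.65 (1.44 without AS replicate 1 and 1.20 without AS replicate 2, over more members) against 3.42 for erythroid markers, but their median of 1.14 CPM in AS is near the floor and their members went both ways. Blood formation in the SS liver, or immature cells in the blood, may also account for the rise, and neither was tested.

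Lists of hepatocyte metabolism fell by camera with its preset correlation, but 0 of the 8 were called with an estimated correlation (adjusted p = 0.0725 to 0.404). A trend on gene length is argued against as the whole cause, since 7 of the 8 lower lists kept that preset call with the trend removed, and male-biased genes lost it. Dilution of hepatocyte RNA by RNA of other cells, which would lower hepatocyte transcripts alike, stays open. The lower lists were set against the 20 most abundant transcripts outside them, ranked by AS mean CPM with Rn45s left out. Against these, the lower lists differed between SS and AS by -0.051 on the log2 scale, with a 95% interval of -0.81 to 0.71. The median log2 change was -0.60 for those abundant transcripts and -0.52 for the genes of the lower lists. These medians are close, but neither set moved alike. Single abundant transcripts ran from -1.15 (Serpina3k) to 0.075 (Trf), and the lower lists had medians from -1.18 (female-biased genes) to -0.40 (fatty acid oxidation). In all 5 reference sets were tried, 4 of them after that first result was seen, and 1 of the 5 gave an interval that excludes 0 (pericentral genes, -1.17 to -0.43), while transcription factors (-1.08 to 0.06), canalicular export genes (-1.75 to 0.70) and these 3 lists pooled (-1.28 to 0.10) did not, so the pericentral value is not taken as deciding. An effect of the sickle genotype on hepatocytes also stays open, untested.

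More genes were called higher than lower in SS. Stray reads in SS replicate 1 are argued against, since 83.7% of calls were higher without it. Scaling between libraries stays open: at least 94.3% of calls were higher under each of 3 other scalings, but these moved the median log2 change of all genes by -0.043, 0.011 and 0.28, so none lowered SS enough to test it. With AS replicate 1 and SS replicate 3 left out together, 346 genes were called higher and 316 lower, so the excess was not seen in that setting, although more genes were called in both directions. A genotype effect stays open, untested.

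The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The genotype split called 122 genes and the highest other split 1, and as many calls came in 1 of the 10 splits. For lists, the genotype split called 17 and the highest other split 15, again with 1 of the 10 splits as high. Every other split has both genotypes on both sides, in unequal numbers. Such a split keeps part of the genotype difference and adds the rest to the spread within groups. Its calls are therefore not those expected without a genotype difference.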

How the results depend on the processing

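The alternatives chosen after seeing the data were those that leave out 2 libraries together, sum AS replicates 2 and 3, or remove a length or GC trend. All 122 called genes kept their sign in each alternative that tested them, and 120 of 120 with a length or GC trend removed. All 122 differed at least 2-fold in the main fit, so a change of sign was unlikely from the start. Of 31 named called genes, 10 kept their call with each library left out in turn. Over the named genes, 736 of 893 comparisons with an alternative kept direction and side of the threshold, 135 lost the threshold and 16 gained it. For lists, 515 of 589 did, 38 lost it and 18 gained it. With library totals alone the median of all genes moved by 0.28 on the log2 scale. At these depths and with 3 libraries per group, 5.6% of simulated 2-fold changes were found.

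Called genes numbered 217 (188 higher, 29 lower) with no filter, 369 (276, 93) by DESeq2, 31 (30, 1) by limma-voom, 31 (31, 0) with AS replicates 2 and 3 summed, and 662 (346, 316) without AS replicate 1 and SS replicate 3. Genes lower in SS numbered 4 with upper-quartile factors, 1 with library totals and 14 with the length trend removed. Leaving out each library in turn gave 22 to 99 calls, 22 to 85 higher and 0 to 15 lower; 14 to 20 lists, 7 to 11 higher and 7 to 10 lower. Lists numbered 0 (0 higher, 0 lower) with an estimated correlation and 9 (5, 4) by fry; 13 were lower without both outlying libraries. The cause was not tested.

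With the replicate number as a block, 460 genes were called (367 higher, 93 lower). Same-numbered libraries had correlations of 0.0497, -0.12 and 0.193 between their deviations from the group mean. Not every AS library correlated best with the SS library of its own number. With 3 libraries per group, these values cannot tell whether the numbers pair the samples.

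Directions turned for Abcc2 (-0.63 without SS replicate 3, -0.91 without both outlying libraries), Cyp7a1 (-0.41 without SS replicate 3), Krt19 (-0.37 without SS replicate 1) and Xist (-0.047 without AS replicate 1, -0.37 without both). Leave-one-out ranges were -0.63 to 0.99, -0.41 to 0.80, -0.37 to 0.70 and -0.047 to 0.68. Lists not called also turned. Endothelial markers did with no filter (adjusted p 0.902), without AS replicate 1 (0.618), without SS replicate 3 (0.154), without both (0.0244) and without the length trend (0.806). Lipogenesis did with median-ratio factors (0.988), the block (0.589), without AS replicate 2 (0.426), AS replicate 3 (0.527) or SS replicate 1 (0.728), with AS 2 and 3 summed (0.471), without the GC trend (0.996) and by fry (0.830). The clock did without AS replicate 3 (0.835), without SS replicate 2 (0.870) and by fry (0.925). The stress response did without SS replicate 3 (0.856) and without both (0.424). Over leave-one-out fits their adjusted p ran from 0.154 to 0.807, 0.0133 to 0.987, 0.126 to 0.931 and 0.123 to 0.856. The cause was not tested.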

Other observations

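Further called genes, chosen after their values were seen, are in none of the fixed lists, although some bear on red cells or the cell cycle. Bpgm, which makes the red cell regulator of hemoglobin oxygen affinity, went from 25.2 to 144 CPM (log2 change 2.52, SE 0.257, edgeR adjusted p = 0.00193). Cdkn1a, the p53 target that halts the cell cycle, rose by 2.47 on the log2 scale (SE 0.431, edgeR adjusted p = 0.0322). Gadd45a, a damage response gene, rose by 1.89 (SE 0.362, edgeR adjusted p = 0.0444). For Cdkn1a, AS replicate 1 had 13.9 CPM, against 5.80 and 4.01 CPM in AS replicates 2 and 3. Tff3, a trefoil peptide of mucous epithelia, had 0 counts over the AS libraries and 174 over the SS libraries (edgeR adjusted p = 0.0154). That is 46.1-fold higher against a floor of 3 counts over the group, with a lower 95% counting bound of 37.1-fold. Lpl, lipoprotein lipase, went from 65.1 to 365 CPM (log2 change 2.49, SE 0.486, edgeR adjusted p = 0.0462), with 294, 617 and 183 CPM in SS replicates 1, 2 and 3. Of all 122 called genes, 100, 97 and 85 lost their call without AS replicates 1, 2 and 3 in turn. Without SS replicates 1, 2 and 3 in turn, 53, 97 and 52 did.

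Single genes rose in lists that were not described as groups above. Rsad2, an antiviral interferon-induced enzyme, went from 10.9 ± 2.85 to 72.0 ± 10.8 CPM (log2 change 2.71, SE 0.285, edgeR adjusted p = 0.00193), as the 1 called member of 27 interferon response genes (2 adjusted over the list alone). The interferon list rose at the threshold (camera adjusted p = 0.0469, adjusted p = 0.618 with an estimated correlation), and its adjusted p was 0.158, 0.0779, 0.165 and 0.861 without AS replicate 1, AS replicate 3, SS replicate 1 or SS replicate 2. Atf3 and Asns, both of the integrated stress response, rose by 3.47 (SE 0.667) and 2.21 (SE 0.439), while that list was not called (camera adjusted p = 0.403). Their calls each ended in 5 of the 6 fits that left out a library, and the log2 change of Atf3 was 2.62 without SS replicate 2 and 4.24 without AS replicate 3. Plin4, a lipid droplet coat protein, rose by 3.85 (SE 0.727) in a lipogenesis list that was not called (adjusted p = 0.976), and its call ended in each of the 6 fits that left out a library, at a log2 change of 2.90 without SS replicate 3. Lists for NF-kB (adjusted p = 0.509), glutathione (0.0732), lymphocytes (0.108), endothelium (0.943), the clock (0.697), hypoxia (0.314) and pericentral hepatocytes (0.462) were not called by the planned test. The glutathione list rose in 7 alternatives, among them library totals alone (0.0281), the length trend removed (0.00512), and those without AS replicate 2 (0.0246) or SS replicate 3 (0.00595). The lymphocyte list rose in 4, among them the length trend removed (0.0269) and those without AS replicate 2 (0.0103) or SS replicate 1 (0.0405). Clock genes fell without AS replicate 1 and SS replicate 3 together (0.000828), as did lipogenesis genes (0.00993), which also fell without AS replicate 1 alone (0.0133). All of these are camera adjusted p-values.

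The replaced beta-globin locus gave a hypothesis that was written before its test: a passenger interval around it may differ between SS and AS. Within 10 Mb of it, 1 of 118 tested genes was called (Tsku), against 119 of 12410 elsewhere (one-sided Fisher exact p = 0.681). The odds ratio has an upper 95% bound of 5.11, so the test leaves it undecided.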
